A study of Rattus norvegicus with 4 samples.

How the data were processed

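Single-colour oligonucleotide arrays for the whole rat genome were used on laser-captured tissue of the rat crista ampullaris, 2 arrays of the superficial hair cell layer and 2 of the underlying supporting cell layer. Per the labels' protocols, the hair cell layer was captured first and the supporting cell bodies left on the basal lamina in a second pass, RNA was extracted with a column kit for small samples, and polyadenylated RNA was amplified linearly into biotin-labelled cRNA and stained with a fluorescent dye. Per the file headers, the slides were quantified with CodeLink Expression Analysis 4.0.0.23520. Each deposited scanner file gives, per spot, a raw intensity that is already corrected for local background (some values are below 0), a normalized intensity, which is the raw value divided by the array's median, and a quality flag. The deposited series table holds the normalized intensity of the scanner files. Its columns equalled the scanner values within 1e-06 in all 35125 rows on 3 arrays. The column of supporting cell layer replicate 2 was shifted: 3 rows were equal as aligned and 35035 after a shift of 2 rows. That column was therefore not used, and the scanner files were. The column medians of the table were close to 1 by construction; scale and centring are those of the scanner software, and any further processing is not given in the sources used here.

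Probes were named from the platform annotation supplied for the series table, matched by the values of the 3 equal columns, with symbols updated through gene identifiers to the GRCr8 RefSeq annotation. Of 33849 gene probes, 16720 had 1 gene symbol there, 192 were named through a RefSeq accession and 19 through the file's own description. A further 165 matched several genes, 10 had a RefSeq accession of another gene than the platform's, and 16743 had no gene named here; none of these was named. The accession of the scanner file equalled the platform's for 81.3% of the annotated probes, and the RefSeq gene was the same in 4391 of 4401 probes that could be compared. The named probes covered 12339 genes.

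Control spots were left out, as were spots flagged as contaminated, irregular or failed in manufacturing (621 contaminated or irregular spots on hair cell layer replicate 1, and 48, 106 and 216 on the other arrays), while saturated spots were kept. The raw intensities were quantile-normalized between the 4 arrays, raised to a floor of 0.1 of the normalized median and taken to log2 values, in R 4.3.3. Probes flagged good or saturated on at least 2 of the 4 arrays were tested, 16483 in all, counted without regard to the layers. The lowest detected normalized intensity was 13.9, 18.5, 26.6 and 28.3 on hair cell layer arrays 1 and 2 and supporting cell layer arrays 1 and 2, and it set the lower limits of fold for probes not above background in a layer: the mean of the brighter layer's log2 values against the mean, per array, of the higher of this limit and the probe's own value. The median signal of the negative control spots was 5.36, 4.78, 4.28 and 4.15 on the same arrays.

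Each probe was tested with limma 3.58.1 (lmFit and eBayes without an intensity trend, no block, two-sided) with Benjamini-Hochberg adjustment over all tested probes, and called at an adjusted p under 0.05. The prior had 1.31 degrees of freedom and an SD of 0.107 on the log2 scale. For a gene with several probes the brightest by mean over the 4 arrays gave the value. The 23 gene lists (hair cells, supporting cells, trophic factors and their receptors, IGF binding proteins, 8 lists of other cell types, and functional groups) were fixed before the data were examined. They were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were run beside it. These tests used the members with a value on all 4 arrays, while counts and medians of a list are over all tested members. Of the 23 lists, 2 passed with the preset correlation, 0 with an estimated one and 18 with fry, which tests whether the genes of a list move one way on balance and does not compare them with other genes.

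The named genes followed a rule fixed before the data were examined: the 15 largest changes in each direction among called, named probes with both arrays of 1 layer above both of the other, every called member of the hair cell, supporting cell, trophic factor and receptor lists, the larger called and the brighter members of the other lists, and well known genes of hair cells, supporting cells and trophic signalling whether called or not. The 6 genes named first among probes detected on all 4 arrays, the 5′ and 3′ control genes and the examples from second lists in the closing section were chosen after values were seen. So was the rule for usable control probes, the last of 3 tried: at least 4 detected spots of 8 in 1 layer, an undetected layer held at its detection limit, and no probe whose limit has the wrong sign. The control transcripts given are not the complete set, since 1 is not reported here.

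The procedure was tested on simulated data for this comparison: signals were drawn for the real probes from their means and replicate spread. The 200 probes changed among 16483 tested were taken from those detected on all 4 arrays. Recovery of changes in probes not detected on every array was therefore not tested. With 50 probes per change, 38 of those lowered 4-fold and 40 of those raised 4-fold were called in the right direction, as were 13 lowered and 14 raised 2-fold. Unchanged probes made up 7.08% of the calls, and 0 probes were called with none changed. A list of 20 genes raised 2-fold passed with the preset correlation (limma's camera, adjusted p = 3.87e-26). With an estimated correlation its p was 0.00699 by limma's camera, and 0.168 after adjustment over 24 lists, so that the simulated list was missed there. Noise was drawn independently for each probe, so the simulation does not test the preset correlation between genes. Far fewer probes were changed than were called in the data, so normalization under many changes was not tested either. Alternatives were median scaling, the scanner software's normalized values, other floors, no filter and a stricter filter on dim probes, an intensity trend, a 2-fold minimum, outlier flags kept, the replicate number as a block, each replicate left out in turn, and the mean over a gene's probes. Slide could not be a block, since each slide held 1 array, and the files give no scan date that holds over 1 array. Uncorrected background columns were not among those used here, so no other background correction was run. Figures were drawn with matplotlib 3.10.9 from tables made with R and with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.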

Results

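Gene expression was measured in the rat crista ampullaris, the sensory epithelium that detects head rotation in each semicircular canal of the inner ear. Laser capture microdissection took the superficial layer, which holds type I and type II hair cells with the cytoplasm of supporting cells between them, and separately the layer of supporting cell bodies that rests on the basal lamina. Each layer was measured on 2 single-colour whole-genome oligonucleotide arrays after linear amplification of its polyadenylated RNA, 4 arrays in all, with 33849 gene probes each. The median raw intensity was 26.5 and 16.98 on the hair cell layer arrays 1 and 2, and 12.1 and 12 on the supporting cell layer arrays 1 and 2. The scanner software called 16511 (48.8%), 15420 (45.6%), 13474 (39.8%) and 13430 (39.7%) of the probes detected on the same arrays. The labels do not say that the 2 arrays of a layer came from separate animals or separate captures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value. Replicate arrays correlated at r = 0.993 in the hair cell layer and 0.994 in the supporting cell layer across the 11059 probes detected on all 4 arrays, which are not independent replicates.

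The study concerned trophic factor expression by supporting cells and its relation to hair cell regeneration, and the design asks which genes differ between the 2 layers. Of 7776 tested genes, each at its brightest probe as in the lists, 65.4% were called, 2195 higher in the supporting cell layer and 2891 higher in the hair cell layer. Counts of called list members near these shares do not set a list apart. Markers of hair cells were higher in the hair cell layer: 17 of 24 tested members of the list were called higher there. Among them were the tip link cadherin Cdh23, the nicotinic receptor subunit Chrna9 and the plasma membrane calcium pump Atp2b2. Trophic factors did not go one way. Of 24 tested, 11 were higher in the supporting cell layer, led by pleiotrophin (Ptn) and ciliary neurotrophic factor (Cntf), and 5 were higher in the hair cell layer, among them Pdgfa and Tgfb3. Endothelial markers were higher in the supporting cell layer, with 9 of 12 tested members called, and markers of supporting cells went both ways. The hair cell and endothelial lists passed limma's camera with a preset correlation (adjusted p = 0.0150 for each) and not with an estimated correlation (adjusted p = 0.818 for each). The endothelial list did not pass among probes detected on all 4 arrays (adjusted p = 0.184). Across the array, 11112 of 16483 tested probes (67.4%) differed by limma with Benjamini-Hochberg adjustment at an adjusted p under 0.05, 5527 higher in the supporting cell layer and 5585 higher in the hair cell layer. Of these, 2914 and 3570 had a fitted change of at least 2-fold, 3107 of them in all on probes detected on all 4 arrays. The count of called probes includes 2051 not above background in the supporting cell layer and 881 in the hair cell layer, whose fitted change is no measure of size. Leaving out 1 hair cell layer array lowered the count by more than 1.5 times, to 7181 without replicate 1 and 7407 without replicate 2. Without any filter on dim probes 6654 probes were called, and with the scanner software's own normalized values 6879.

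**Figure D1:**
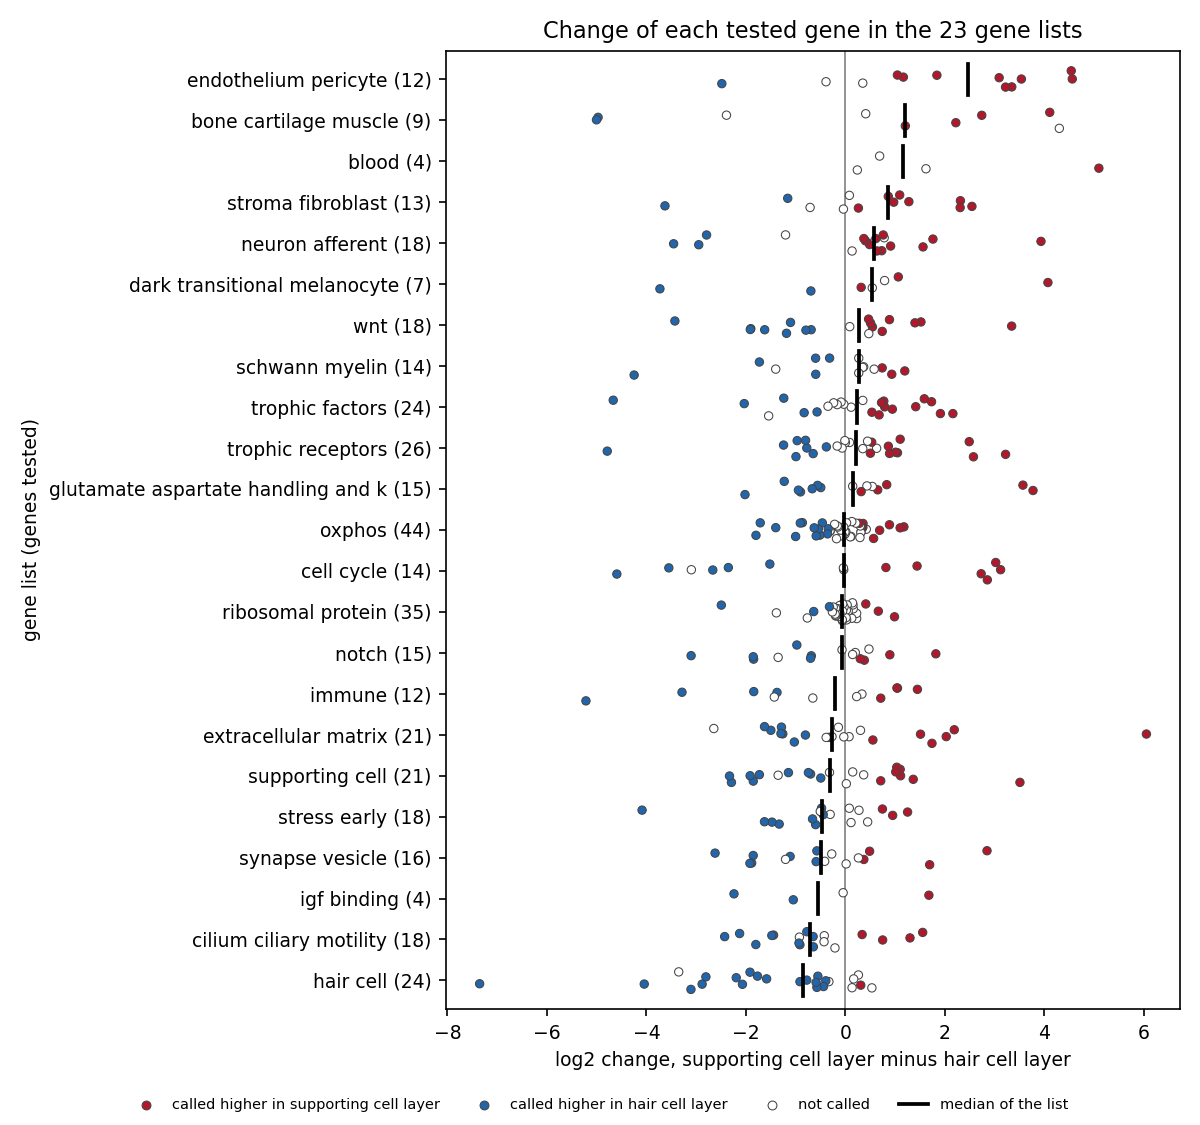
Log2 change (supporting cell layer minus hair cell layer, horizontal axis) of every tested gene in the 23 gene lists fixed before the data were examined, 1 point per gene (its brightest probe) and a bar at each list's median; red points were called higher in the supporting cell layer, blue points higher in the hair cell layer, and open points were not called. The medians of these fitted changes run from -0.84 in the hair cell list to 2.47 in the endothelial list, which is 1.93 with undetected members at their lower limits and 1.11 among probes detected on all 4 arrays.

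A change is given as the supporting cell layer minus the hair cell layer on the log2 scale, with its standard error from limma (2 arrays per layer, except for Pmel, Ctbp2, Cldn5 and Csf1r), and a negative change is a higher signal in the hair cell layer. Where a probe was not above background on either array of a layer, only a lower limit of the fold is given, from the lowest detected signal of those arrays. These limits are approximate, since an undetected probe can read above that signal. In the hair cell list, the camera test with a preset correlation gave an adjusted p of 0.0150 for a lower level in the supporting cell layer, on 22 of 24 tested members. The adjusted p was 0.818 with an estimated correlation. The median change of the list was -0.84. Cdh23 was at least 15.7-fold higher in the hair cell layer and the stereociliary actin bundler Espn at least 3.69-fold higher, both without detected signal in the supporting cell layer. Grxcr1 changed by -3.10 ± 0.13, Chrna9 by -2.88 ± 0.10 and Atp2b2 by -2.80 ± 0.08. The potassium channel Kcnma1 had a fitted fold of 4.57 toward the hair cell layer. No lower limit is known for it, since its undetected signals lay above the lowest detected signal of the supporting cell layer arrays. The calcium-binding proteins oncomodulin (Ocm) and parvalbumin (Pvalb) changed by -2.07 ± 0.07 and -1.58 ± 0.10, Spp1 by -1.92 ± 0.17 and the transduction complex member Cib2 by -1.77 ± 0.11. Smaller changes were called for Triobp (-0.91 ± 0.10), Chrna10 (-0.78 ± 0.10), the synaptic calcium sensor otoferlin Otof (-0.59 ± 0.09), the ribbon protein gene Ctbp2 (-0.57 ± 0.10) and the transcription factors Gfi1 (-0.55 ± 0.11) and Barhl1 (-0.39 ± 0.10). Lhfpl5 had a fitted fold of 1.36 toward the hair cell layer, likewise without a known lower limit. Anxa4 went the other way, with a change of 0.31 ± 0.07. Myosin VIIa (Myo7a) was detected on both hair cell layer arrays and on neither supporting cell layer array, but its difference did not pass the test (adjusted p = 0.0828 by limma, with 2.10-fold as the lower limit). Calretinin (Calb2) had a change of 0.13 ± 0.10 that did not pass the test. No probe was named here for Pou4f3, Atoh1, Otoa or Fgf2.

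Of 21 tested supporting cell markers, 7 were higher in the supporting cell layer, 9 were higher in the hair cell layer and 5 did not pass the test. The list as a whole did not pass the test against other genes (camera adjusted p = 0.916). Higher in the supporting cell layer were the alpha-tectorin gene Tecta (3.51 ± 0.18), the intermediate filament genes Vim (1.37 ± 0.08) and Krt8 (1.01 ± 0.27), and the transcription factors Gata3 (1.11 ± 0.19), Prox1 (1.10 ± 0.14), Gata2 (1.03 ± 0.07) and Sox9 (0.71 ± 0.15). Higher in the hair cell layer were Epcam (-2.33 ± 0.14), otogelin Otog (-2.29 ± 0.07), Notch1 (-1.85 ± 0.07), Sox10 (-1.73 ± 0.13), Cdh2 (-1.14 ± 0.10), the Notch ligand Jag1 (-0.70 ± 0.07) and the glutamate transporter Slc1a3 (-0.49 ± 0.08), together with the tight junction gene Cldn9, at least 3.21-fold. Sox2 changed by -0.74 ± 0.08 at its brighter probe, and its other probe had the opposite sign, so that the mean over both probes was 1.94. The gap junction genes Gjb2 (-0.32 ± 0.11) and Gjb6 (0.02 ± 0.11) and glutamine synthetase Glul (0.15 ± 0.09) did not pass the test.

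Among the 24 tested trophic factors, the 11 higher in the supporting cell layer were Ptn (2.16 ± 0.31), Cntf (1.91 ± 0.23), epiregulin Ereg (1.73 ± 0.08), Bmp6 (1.59 ± 0.20), Csf1 (1.41 ± 0.17), Fgf3 (0.94 ± 0.15), Gdf15 (0.79 ± 0.18), Pdgfb (0.77 ± 0.16), Lif (0.73 ± 0.13), Nrg4 (0.68 ± 0.09) and Vegfa (0.53 ± 0.09). The 5 higher in the hair cell layer were Pdgfa (-2.03 ± 0.09), Tgfb3 (-1.24 ± 0.09), Manf (-0.83 ± 0.15) and Bmp7 (-0.57 ± 0.10), and Ccn3, which was at least 2.57-fold higher there. Igf1 had a change of -0.09 ± 0.07 and midkine Mdk of -0.03 ± 0.11, neither past the test. The probes for the neurotrophins Bdnf and Ntf3 and for Gdnf were near background on all 4 arrays, so no difference was detectable for them. The list as a whole did not pass the test against other genes (camera adjusted p = 0.529), which is no evidence that it behaves like them. Its 11 and 5 of 24 stand beside 2195 and 2891 of all 7776 tested genes. Adjusted over the list alone the same 11 and 5 members passed.

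**Figure D2:**
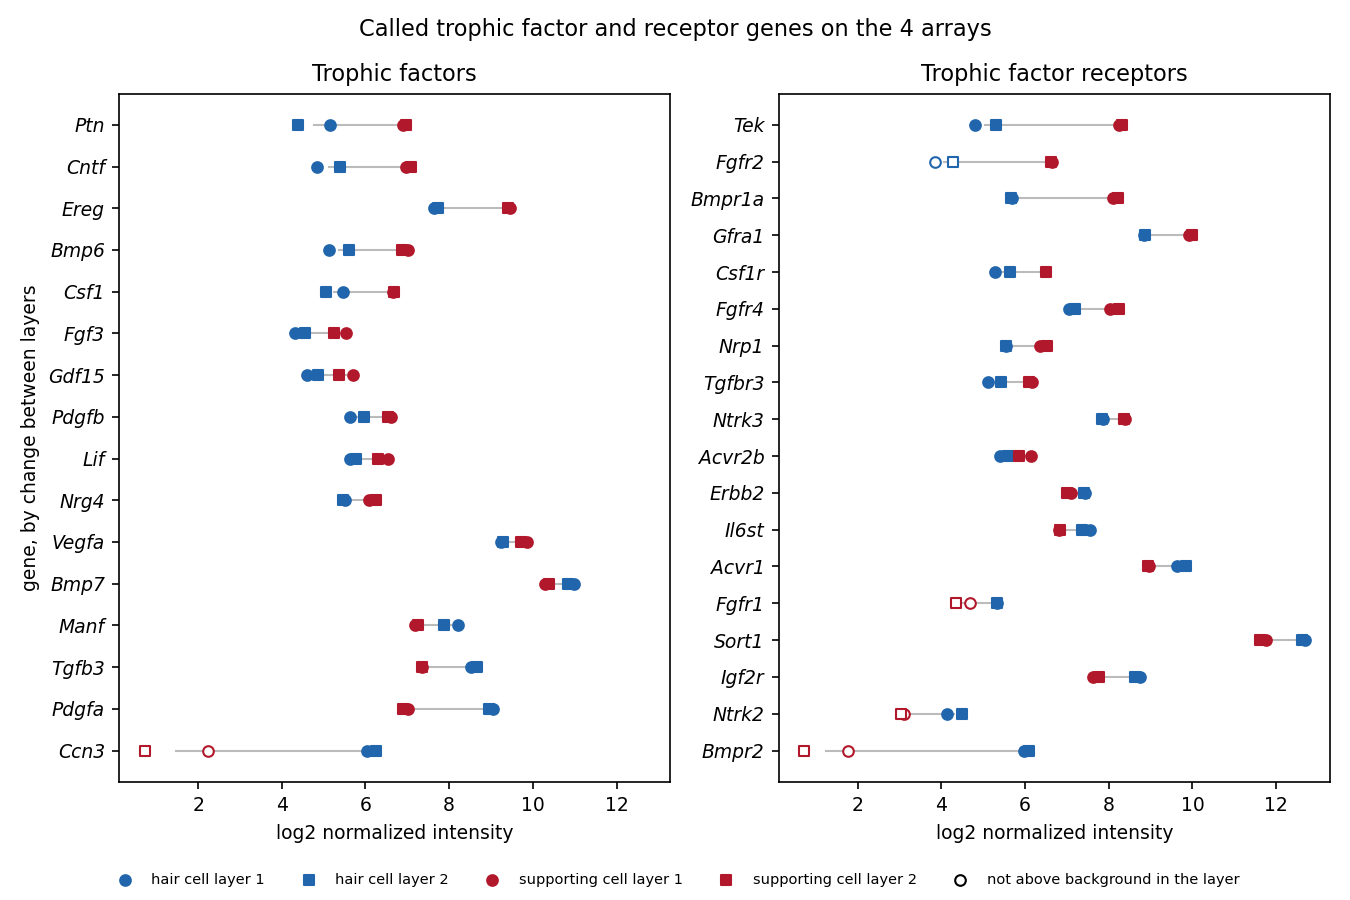
Log2 normalized intensity (horizontal axes) of each called trophic factor gene (left) and trophic factor receptor gene (right) on the 4 arrays, in order of change; blue marks are hair cell layer arrays, red marks supporting cell layer arrays, circles replicate 1 and squares replicate 2, open marks were not above background on either array of that layer, and grey lines join the layer means. Ptn has the largest change among the factors higher in the supporting cell layer, 2.16, and Tek among the receptors detected in both layers, 3.22.

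Of 26 tested trophic factor receptors, 10 were higher in the supporting cell layer, 8 were higher in the hair cell layer and 8 did not pass the test (camera adjusted p = 0.674). The angiopoietin receptor Tek (3.22 ± 0.22) and the BMP receptor Bmpr1a (2.49 ± 0.09) were higher in the supporting cell layer, and Fgfr2 was at least 5.96-fold higher there. The GDNF family co-receptor Gfra1 (1.10 ± 0.07), Csf1r (1.05 ± 0.22), Fgfr4 (1.01 ± 0.12), Nrp1 (0.89 ± 0.09), Tgfbr3 (0.86 ± 0.15), the neurotrophin-3 receptor Ntrk3 (0.53 ± 0.07) and Acvr2b (0.50 ± 0.14) went the same way. Igf2r (-0.99 ± 0.10), Sort1 (-0.97 ± 0.09), Acvr1 (-0.78 ± 0.11), Il6st (-0.65 ± 0.10) and Erbb2 (-0.38 ± 0.08) were higher in the hair cell layer, as were Bmpr2 and Fgfr1, at least 2.39-fold and 1.46-fold. The second probe of Igf2r had the opposite sign. The BDNF receptor Ntrk2 was detected in the hair cell layer alone and was called higher there (adjusted p = 0.00775 by limma). Its mean intensity in that layer, 19.9, lay below the lowest detected on the supporting cell layer arrays, 26.6 and 28.3. The same signal would not have been detected on those arrays, so its detection in the hair cell layer alone is no evidence of a difference, and no fold is given. Egfr (-0.01 ± 0.07) and Igf1r (0.00 ± 0.24) did not pass the test.

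The largest fitted changes were mainly of genes detected in 1 layer. Only lower limits of their fold are known, so they have no order among themselves or against measured changes. Higher in the hair cell layer were the orphan receptor Gpr158 (at least 26.8-fold), Cdh23, Ybey (9.99-fold), Tnfaip8 (17.6-fold), Me2 (11.97-fold), Steap2 (16.1-fold), Itgbl1 (8.21-fold), the kinesin gene Kif27 (34.3-fold), Ccdc90b (8.76-fold), Pign (5.16-fold), Dnase2b (11.8-fold), Nceh1 (7.04-fold), Adat3 (4.41-fold), Ccdc184 (7.01-fold) and the neutral amino acid transporter Slc1a4 (9.08-fold), all as lower limits. The second probe of Me2 had the opposite sign. Higher in the supporting cell layer were Lrif1 (at least 16.7-fold), cystathionine beta-synthase Cbs (25.4-fold), the ubiquitin-like interferon-induced Isg15 (16.2-fold), Txlnb (9.93-fold), C1qtnf12 (21.5-fold), laminin alpha 1 Lama1 (9.88-fold), Tnik (35.7-fold), the organic anion transporter Slco2b1 (17.1-fold), Pitpnm2 (10.5-fold) and Zfp384 (8.19-fold). The replication and mitosis genes Cdc45 (19.2-fold), Dlgap5 (13.3-fold) and Kif20a (8.64-fold) and the alpha-haemoglobin chaperone Ahsp (7.67-fold) belonged to the same group, again as lower limits. Kank3 was detected on all 4 arrays and changed by 5.08 ± 0.08. Ranking only probes detected on all 4 arrays, a choice made after the data were seen, put Manba (-4.40 ± 0.13), Tmem130 (-4.39 ± 0.10) and Sult4a1 (-4.37 ± 0.12) first in the hair cell layer, and Kank3, Pals2 (4.33 ± 0.08) and the AMPA receptor subunit Gria2 (3.93 ± 0.14) first in the supporting cell layer.

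Markers of other cell types also differed between the layers. The endothelial and pericyte list was higher in the supporting cell layer (camera adjusted p = 0.0150, on 11 of 12 tested members), with an adjusted p of 0.818 with an estimated correlation. Its 9 called members included Tie1 (3.54 ± 0.09), the efflux pump Abcb1a (3.35 ± 0.09), Tek, Cldn5 (1.84 ± 0.10) and Pecam1 (1.05 ± 0.11), and the pericyte gene Rgs5 at least 4.33-fold. Vwf went the other way (-2.48 ± 0.16). With each undetected member held at its lower limit the median change was 1.93. With every value raised to the highest detection limit of the 4 arrays it was 1.25, and the list still passed (camera adjusted p = 0.0213). Among probes detected on all 4 arrays, which leave out members undetected in the hair cell layer and keep 8 of the 12, the list no longer passed (camera adjusted p = 0.184, median change 1.11). Of 13 tested connective tissue markers, 8 were higher in the supporting cell layer, among them Mgp (2.31 ± 0.08), Tbx18 (2.31 ± 0.07) and Col1a2 (0.97 ± 0.09), and 2 were higher in the hair cell layer, among them Fbn1, at least 1.36-fold. Col1a1 (0.08 ± 0.13) and Dcn (-0.71 ± 0.24) did not pass the test, nor did the list (camera adjusted p = 0.102). Of 18 tested neuronal markers, 11 were higher in the supporting cell layer, with Gria2, the potassium channel Kcna1 (1.76 ± 0.07) and Gap43 (0.91 ± 0.08), and 3 were higher in the hair cell layer, with the neurofilament gene Nefl at least 3.17-fold (camera adjusted p = 0.0770). Among probes detected on all 4 arrays the neuronal list passed (camera adjusted p = 0.00935, median change 0.73), but that filter leaves out all 3 members higher in the hair cell layer, which were undetected in the supporting cell layer. With an estimated correlation, run in the main setting, the adjusted p of the neuronal list was 0.818.

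Of 4 tested blood cell markers Ahsp alone was called. Median scaling and the scanner software's own values brought the blood list past the test (camera adjusted p = 0.0346 and 0.0345, main value 0.301). With an estimated correlation, run in the main setting, its camera adjusted p was 0.818. Ahsp was not detected in the hair cell layer, so its fitted change is no measure of size. S100a9, which alone of the 4 was detected on all 4 arrays, changed by 0.24 ± 0.23. The other marker lists were divided. Of 14 tested Schwann cell markers 3 were higher in the supporting cell layer, such as Prx (0.93 ± 0.07), and 5 in the hair cell layer, such as Ncam1 (at least 7.02-fold). Of 12 tested immune markers 4 were higher in each layer, with Cd74 (1.04 ± 0.11) on the supporting side and Aif1 (at least 6.26-fold) on the hair cell side. Of 7 tested dark cell, transitional cell and melanocyte markers, 3 were higher in the supporting cell layer, such as Mitf (at least 16.5-fold), and 2 in the hair cell layer, such as Pmel (-3.73 ± 0.10). Of 9 tested bone, cartilage and muscle markers 4 were higher in the supporting cell layer, such as Acan (2.22 ± 0.07), and 2 in the hair cell layer, such as Myh2 (at least 10.9-fold). None of these 4 lists passed as a whole, with camera adjusted p of 0.916, 0.916, 0.419 and 0.529.

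Of the functional lists, none passed the camera test. Of 18 tested cilium genes 10 were higher in the hair cell layer and 4 in the supporting cell layer. The axonemal tektin genes Tekt4 (-2.13 ± 0.10) and Tekt1 (-1.44 ± 0.11) and the radial spoke gene Rsph9 (-1.48 ± 0.09) were higher there, and Kif3a (1.55 ± 0.09) was higher in the supporting cell layer. The list did not pass (camera adjusted p = 0.419). Of 16 tested synapse genes 7 were higher in the hair cell layer, such as Nsf (-1.85 ± 0.07) and Cplx1 (-1.88 ± 0.24), and 4 in the supporting cell layer, such as Napb (2.85 ± 0.09). Extracellular matrix and adhesion genes were divided 6 to 8 of 21 tested, with Col4a1 (2.03 ± 0.16) higher in the supporting cell layer and Sparcl1 (-1.63 ± 0.09) and Tnc (-1.50 ± 0.10) higher in the hair cell layer. In the Notch list 4 of 15 tested were higher in the supporting cell layer, such as Mfng (1.82 ± 0.07), and 6 in the hair cell layer, such as Heyl (-0.98 ± 0.07). In the Wnt list 8 of 18 tested were higher in each layer, with Wif1 (3.34 ± 0.18) on the supporting side and Axin1 (-1.91 ± 0.08) on the hair cell side. Cell cycle genes were divided 6 to 5 of 14 tested. Mcm6 (3.12 ± 0.09) and the cell cycle inhibitor Cdkn1a (2.73 ± 0.08) were higher in the supporting cell layer, as was Cdk1, at least 6.99-fold, while Aurka was at least 4.82-fold higher in the hair cell layer. Of 18 tested stress and early response genes 3 were higher in the supporting cell layer, such as Egr1 (0.95 ± 0.07), and 9 in the hair cell layer, such as Klf6 (-1.63 ± 0.08) and Fos (at least 2.67-fold). Among 15 tested glutamate and potassium handling genes 5 were higher in the supporting cell layer, such as connexin 43 Gja1 (at least 9.04-fold), and 7 in the hair cell layer, such as the potassium channel Kcnk1 (-2.02 ± 0.11). Of 4 tested IGF binding proteins Igfbp7 (1.68 ± 0.10) was higher in the supporting cell layer, and Igfbp3 (-2.24 ± 0.07) and Igfbp5 (-1.05 ± 0.10) in the hair cell layer. Oxidative phosphorylation genes were divided 9 to 14 of 44 tested, with Ndufs3 (1.18 ± 0.08) and Atp5f1d (-1.80 ± 0.10) at the ends. Of 35 tested ribosomal protein genes 29 did not pass, 3 were higher in each layer, and Rps6 had a change of -0.12 ± 0.07. The camera adjusted p of the last 10 lists lay between 0.861 and 0.935. Adjusted over the list alone, the counts of 18 of the 23 lists stayed the same. In the other 5 (ribosomal, oxidative phosphorylation, stress, cell cycle, and bone, cartilage and muscle) they moved, most for ribosomal protein genes, to 2 and 0. The median, the mean and the camera direction differed in sign in 7 lists: cell cycle, extracellular matrix, immune, Notch, oxidative phosphorylation, Schwann cell and Wnt.

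Probes of the same gene did not always go the same way. Of 516 genes whose 2 brightest tested probes were both called, 173 (33.5%) had them in opposite directions, and the changes of the 2 probes correlated at r = 0.24 across 1189 genes, which are not independent replicates. Among probes detected on all 4 arrays with a mean log2 signal above 7, 24 of 137 such genes (17.5%) had opposite directions. The array also carries control probes at the 5′ and 3′ ends of transcripts, of which 5 are given here. In the glycolytic gene Pgk1, detected at both ends in both layers, the 5′ probes changed by 1.74 and the 3′ probes by 0.43. In the hexokinase gene Hk1 the 5′ probes were detected on 0 of 24 spots in the hair cell layer and on 23 of 24 in the supporting cell layer, a change of at least 1.98, against 0.07 at the 3′ end. The others depended on which probes were counted. Leaving out probes detected on fewer than 4 of 8 spots in both layers, a choice made after the values were seen, gave 2.16 and 0.75 at the 5′ and 3′ ends of Pc, and -0.29 and -0.63 in Sdha, and left Hprt without a usable 5′ probe. With every probe as measured, the 5′ change minus the 3′ change was 0.16 in Pc, 0.48 in Sdha and -0.21 in Hprt.

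**Figure D3:**
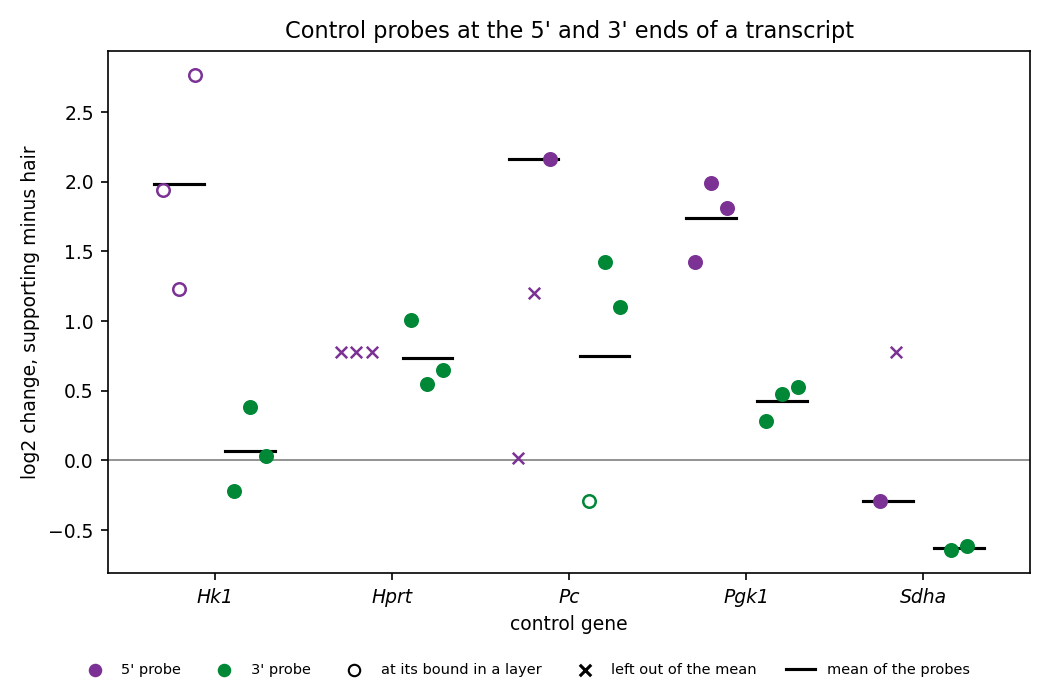
Log2 change (supporting cell layer minus hair cell layer, vertical axis) of the control probes at the 5′ end (purple) and 3′ end (green) of 5 transcripts, 1 point per probe averaged over its repeat spots and the 2 arrays of each layer. Bars are means, open points are held at their lower limit in a layer without detected signal, and crosses were left out of the means; the mean 5′ change lies above the mean 3′ change in the 4 of these transcripts with both means, and Hprt has no 5′ mean.

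The calls rest on limma's moderated test with 2 arrays against 2. Both arrays of 1 layer lay above both of the other for 89.2% of 15984 tested probes with a value on all 4 arrays. Chance gives 33.3% only if the 4 arrays are independent. The labels do not say that the 2 arrays of a layer were separate captures. The 89.2% therefore shows that the samples differed, and cannot tell a difference between layers from one between samples. Of the genes named here, Tecta, Ptn, Fgf3, Gdf15 and Cd74 were detected on 1 of the 2 hair cell layer arrays, and Spp1 and Cplx1 on 1 of the 2 supporting cell layer arrays. Pmel and Ctbp2 had no usable value on hair cell layer replicate 1, Cldn5 none on supporting cell layer replicate 2 and Csf1r none on supporting cell layer replicate 1. The tests of these genes set 1 array against 2 and assume that the lone array varies like the others. An exact permutation test of a single probe cannot go below p = 0.333 with 2 against 2.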

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

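The test of dim signal and the rule for usable control probes were chosen only after the results were seen, and the direction tested for clone ends was taken from control probes already seen. Control probes at both ends of a transcript lie outside the comparison of gene probes, and the log2 ratio of their 5′ to 3′ signal was higher in the supporting cell layer by at least 1.92 in Hk1, by 1.42 in Pc, by 1.31 in Pgk1 and by 0.34 in Sdha. This rule, the last of 3 tried, favours that direction: it left out Hprt, at -0.21 with every probe as measured and 0.04 with undetected layers held at their limit, and raised Pc. Under those first 2 rules Pc stood at 0.16 and 0.38, Sdha at 0.48 and 0.87, Hk1 at 3.36 and 1.92 and Pgk1 at 1.31 in both. These are not all of the control transcripts, so no direction is drawn for the set.

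The pattern weighed is that probes of the same gene changed in opposite directions, in 173 of 516 genes with both of their 2 brightest probes called (33.5%). Signal near background does not account for all of it, since 17.5% (95% exact binomial interval 11.6 to 24.9%) of 137 such genes with bright probes detected on all 4 arrays still had opposite directions. Nor do probes named for the wrong gene, since 19.4% (10.8 to 30.9%) of 67 genes with both probes designed on RefSeq transcripts did, dim probes included. Both shares are below the one over all tested probes, and either could be part of it. With RefSeq probes detected on all 4 arrays, 6 of 40 such genes (15%, 5.71 to 29.8%) had opposite directions. So wide an interval leaves open whether the 2 explanations together account for most of it. The distance of a probe from the end of the transcript stays open: in 195 genes with a probe from each end of a cDNA clone the 5′ change minus the 3′ change had a median of 0.37, with a bootstrap 95% interval of -0.06 to 0.57 that includes 0, and in the 71 genes with both probes detected on all 4 arrays a median of 0.43 (0.07 to 0.65), a set looked at afterwards. Transcript variants that differ between the layers are a biological explanation that was not tested.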

How the results depend on the processing

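The floor at the detection limit was added only after the data were seen, and the other alternatives were chosen before. The count of called probes, 11112, fell by more than 1.5 times with the scanner software's values (6879), without a filter on dim probes (6654) and with a 2-fold minimum (6484, fewer by construction), and with all 4 arrays otherwise stayed between 8434 and 12125. Their split moved most in probes detected on all 4 arrays, where 4836 were higher in the supporting cell layer and 3598 in the hair cell layer. Leaving out each array in turn gave 7181 to 9991 probes called, with a lone array assumed to vary like the other layer's. Probes called in the main setting and under an alternative had the same direction in every case, which is nearly certain for probes called in both. Of the main calls 51.9% were kept without a filter on dim probes, 55.9% with the scanner software's values and 71.2% with median scaling. With the scanner software's values the standard error was 0.46 for each of Egfr, Gjb2, Igf1, Mdk and Rps6, against 0.07 for Egfr in the main setting. That fit gave these genes the same spread instead of their own. Fewer calls there therefore need not reflect the normalized values themselves. Other causes were not tested.

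The replicate numbers were not shown to pair arrays: deviations of same-numbered arrays correlated at -0.002 over tested probes. With the replicate number as a block 8756 probes were called, 8633 of them also called without it, and 2 lists.

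The number of lists past the test was 2, or 3 with median scaling and with the scanner software's values, 0 with an estimated correlation and 18 with fry, which asks another question. Without each array in turn it stayed at 2. Among probes detected on all 4 arrays the endothelial list was lost (adjusted p = 0.184 by limma's camera, median 1.11 from 2.47) and the neuronal list gained, but this filter leaves out endothelial members undetected in the hair cell layer and the 3 neuronal members higher there; the hair cell list passed under every rerun of camera with the preset correlation.

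Median scaling moved the median change of all tested probes to 0.10 and the scanner software's values to 0.14, from 0.01. Of 181 named genes, 168 of them called, the sign turned in few, mostly with changes near 0 that no fit called: with median scaling Egfr (0.075), Gjb2 (0.041), Mdk (0.086) and Rps6 (0.44), and with the scanner software's values Egfr (0.11), Gjb2 (0.074), Igf1 (0.019), Mdk (0.12) and Rps6 (0.48). Of these, Rps6 and Gjb2 moved furthest beyond the shift of all probes. The called change of Sox2, -0.74, became 1.94 as the mean over its probes, since the dimmer probe went the other way. Leaving out each array in turn gave Egfr -0.036 to 0.015, Gjb6 -0.094 to 0.13, Igf1r -0.29 to 0.29, Mdk -0.14 to 0.076 and Col1a1 -0.060 to 0.22. Calls were lost for 31 and 32 of these genes without hair cell layer replicate 1 or 2, 18 and 13 without supporting cell layer replicate 1 or 2, 21 with median scaling, 39 with the scanner software's values, 40 without a filter and 37 with a 2-fold minimum.

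Normexp background correction was not run, since the intensity used is already corrected, nor was a slide or scan date block, since no slide or date was shared by 2 arrays. Signal over background limits the folds: 2051 called probes were not above background in the supporting cell layer and 881 in the hair cell layer, and for these a fitted change is no measure of size.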

Other observations

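The test of the scaling was chosen only after the result was seen; the tests of second lists were set before the second lists were looked at, but after the first lists and the leading interferon-induced genes had been seen. In a second endothelial list that shares no gene with the first, 12 of 24 tested members were higher in the supporting cell layer, 2 were higher in the hair cell layer and 10 did not pass limma's test. Higher in the supporting cell layer were S1pr1 (at least 7.66-fold), the endothelial transcription factor Erg (at least 6.41-fold), Egfl7 (at least 3.78-fold), Nostrin (1.76 ± 0.07), Tm4sf1 (1.25 ± 0.07) and the glucose transporter Slc2a1 (0.78 ± 0.09). Ece1 (-1.67 ± 0.08) and Arhgef15 (-0.45 ± 0.10) were higher in the hair cell layer.

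Of the interferon-induced genes, Isg15 was among the largest fitted changes toward the supporting cell layer, and Usp18 (3.62 ± 0.07) and Samd9l (3.47 ± 0.11) were among the largest of probes detected on all 4 arrays. Of 23 other tested interferon-induced genes 11 were higher there, such as Mx2 (at least 6.77-fold at its brighter probe, the other having the opposite sign), Psmb9 (2.16 ± 0.18) and Irf7 (1.06 ± 0.17), 6 were higher in the hair cell layer, such as Parp14 (-1.71 ± 0.07) and Oasl (at least 2.78-fold), and 6 did not pass. The hypothesis that interferon-induced genes are higher in the supporting cell layer as a group was not settled: the median of the list without the genes first seen was 0.15, at the 83.2nd percentile of 10000 random lists matched on mean signal, between the bounds set beforehand for a shift and for none.

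The endothelial genes higher in the supporting cell layer were weighed against other tissue in the capture and against the scaling. The first list also passed with median scaling and with the scanner software's values, at adjusted p of at most 2.76e-05 by limma's camera with the preset correlation. With an estimated correlation, run in the main setting, its adjusted p was 0.818. Both settings divide each array by its median, so they are nearly the same check. They show only that the result did not need quantile normalization. Camera compares a list with other genes, so they cannot exclude a difference between arrays that depends on intensity. Standard errors of Egfr, Gjb2, Mdk and Rps6 were nearly equal there (0.32 to 0.33 with median scaling, 0.46 with the scanner software's values). The smaller adjusted p may come from this spread and is not read as a stronger result. Vessel cells captured with the supporting cell bodies are a candidate explanation: the median of the second list, 0.48, lay at the 98.8th percentile of the matched random lists, although the first neuronal and connective tissue lists also lay high, at the 98.7th and 99.9th. Of its 24 genes 19 were also detected on both hair cell layer arrays. Of the brighter endothelial genes Ece1 fell from 569 to 179 and Vwf from 293 to 52.4 in intensity from the hair cell to the supporting cell layer. Slc2a1 rose from 590 to 1011, Tm4sf1 from 413 to 980 and Cldn5, with a lone supporting cell layer array, from 411 to 1471. Connective tissue captured with them stays open, with 6 of 16 tested members of a second list higher in the supporting cell layer and 4 in the hair cell layer, a median of 0.18 at the 86.2nd percentile, below that of the first connective tissue list, and expression of endothelial genes by supporting cells themselves was not tested.

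All tested probes made from 1 end of a cDNA clone were also compared without matching by gene, although 195 genes have a probe in both sets. The 1827 probes on 5′ ends had a median change of 0.26 and the 9807 on 3′ ends a median of -0.01. In the deposited series table, the column of supporting cell layer replicate 2 matched its scanner file only after a shift of 2 rows (35035 of 35125 values, against 3 as aligned), so a comparison made from that table by row would set different probes side by side on that array.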
